A study of Mus musculus with 2 samples.

How the data were processed

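Femur bone marrow and BMP-2 induced ectopic bone of mice were each profiled in 1 single-cell RNA library. Per the labels, hematopoietic cells came from wild-type mice and CAR cells from Cxcl12-GFP mice. Tissue for the CAR cells was digested with collagenase, hematopoietic and endothelial cells were depleted on magnetic columns, and live cells were sorted. Both fractions were combined before loading on the Chromium Next GEM 3ʹ v3.1 kit, so the stromal share of each library reflects the mixing. The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 7.0.1 per the file headers and with the genome build GRCm39 per the submitters' processing notes. Values were checked to be whole numbers, and no deposited barcode had fewer than 500 UMIs. The annotation behind the counts is not stated, so genes are given by the symbol and identifier of the feature lists, without coordinates. The femur library held 123009924 UMIs over 11148 barcodes and the ectopic library 86018367 over 7214, with 34184 genes listed.

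Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, which left 10665 femur and 6794 ectopic cells. A doublet score after the method of Scrublet was computed per library, and the highest-scoring cells were left out at 0.8% per 1000 cells, 910 femur and 369 ectopic. Both libraries were clustered together with scanpy 1.11.5 and igraph 0.11.9. Counts were scaled to 10000 per cell and logged, and 2000 variable genes without Xist, Y-linked, mitochondrial and ribosomal genes gave 30 principal components. A graph of 15 neighbours was cut by the Leiden method at resolution 1. Marker lists of 25 cell types were fixed before the data were seen. The naming rule was set after the clusters were seen. It takes the type with the most markers among the 10 genes of highest fold against all other cells (genes from 100 UMIs, 10 CPM added), or with none there the type of highest mean marker fold. A cluster stayed unnamed with fewer than 3 markers of that type above other cells, or with low UMIs (below 0.333 of the median) and no marker among the 10. Class names mean cells like that type. The genes that lead a cluster are not results. Shares inside a class are given beside values that they can set. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, with edgeR used only for TMM factors.

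With 1 library per group no test was possible, and no p-value or error was taken from cells. Shares of hematopoietic classes were taken over cells outside stromal classes, with exact binomial (Clopper-Pearson) 95% intervals. For genes, UMIs were summed over the cells of a class and library and scaled to CPM by the UMIs of that sum. Ratios are ectopic over femur, with exact conditional binomial intervals of 2 Poisson counts. A library at 0 UMIs was set to 3 UMIs and its fold is a lower bound. All intervals and floors cover counting error only. Members of a gene list counted as measured from 50 UMIs over both libraries and as higher or lower from a 1.5-fold ratio, a rule of size and not a test. The median log2 ratio of a list was placed among 10000 random lists of the same size, with each member drawn from the 50 genes on either side of it in expression, as a description of these libraries. Its interval came from 1000 redraws of the counts. Shares of CAR-like cells with a UMI were taken after thinning each cell to 3000 UMIs, and cells below that number were left out. To set classes side by side, class sums were thinned to 1452997 UMIs, the smallest class sum.

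Genes were named by a rule fixed before the data. In CAR-like cells it takes every niche factor and CAR identity gene with at least 50 UMIs. For each other fixed list that fits a class it takes up to the 2 highest and 2 lowest ratios. For each class it takes the 10 highest and 10 lowest ratios among genes with at least 100 CPM in 1 library, at least 50 UMIs and at least 0.5 times the CPM of all other cells in the library where the gene was higher. Mitochondrial, ribosomal, globin, immunoglobulin, Xist and Y-linked genes and unnamed gene models were left out of this last part. A few genes that the rule takes are not reported here. Genes named outside the rule, among them Adipoq, Ibsp, Col1a1 and EGFP in the detection of single cells and the genes that label clusters, were chosen after their values were seen.

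The alternatives fixed beforehand were a minimum of 1500 UMIs or at most 5% mitochondrial UMIs per cell, no doublet removal, Leiden resolutions of 2 and 0.5, clustering of each library alone, TMM or median-of-ratios scaling, means of per-cell CPM, thinned cells, only cells with no Ptprc UMI, a minimum of 20 UMIs, a fold of 2 and no thinning for detection. CAR-like cells without the low-UMI cluster, and only those with an EGFP UMI, were added after the data were seen. The procedure was tested on simulated data drawn from the summed CAR-like counts. There 60 of 63 genes changed 2-fold and 62 of 62 changed 4-fold passed the 1.5-fold rule, as did 32 of 61 changed exactly 1.5-fold and 264 of 8563 unchanged genes. Intervals held the true value for 95.8% of unchanged genes. The simulated counts were independent Poisson draws, the model that the intervals assume. They leave out the gathering of UMIs in a few cells, so these rates do not carry over to genes where that occurs. A doubled list of 15 genes had a median of 0.99 at percentile 100, and 14 unchanged lists had medians of -0.07 to 0.30 at percentiles up to 99.1, the highest for a list of 4 measured genes. Classes with fewer than 100 cells in either library were given shares only, and lists that fit none of the 7 classes compared were not used here.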

Results

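Single-cell RNA sequencing by the 10x Genomics Chromium 3ʹ v3.1 chemistry was available for 2 mouse libraries, 1 per tissue. The first came from femur bone marrow and the other from the marrow of ectopic bone, which formed under the skin within 4 weeks of an implant of bone morphogenetic protein 2 (BMP-2, 8 µg) on β-tricalcium phosphate (40 mg). Each library combined hematopoietic cells of wild-type mice with CXCL12-abundant reticular (CAR) cells of Cxcl12-GFP reporter mice. CAR cells are the perivascular stromal cells of marrow that secrete CXCL12 and stem cell factor and carry leptin receptor. The femur matrix held 11148 barcodes and 123009924 UMIs (median 8377.5 per barcode), and the ectopic matrix held 7214 barcodes and 86018367 UMIs (median 8803.5). After filtering, 9755 femur and 6425 ectopic cells were kept. With 1 library per group, no difference was tested and none had a replicate check. Intervals of shares, levels and ratios are exact 95% intervals, those of list medians came from redraws of the counts, and all cover counting error only.

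The first comparison asked whether the hematopoietic classes of femur marrow were present in ectopic marrow, and at which shares. Neutrophils and B lineage cells were the largest classes in both tissues, and every class named in the femur library was also seen in the ectopic library. B lineage cells, the antibody-forming lineage, made up 26.8% (25.96 to 27.8) of the 9520 femur cells outside stromal classes and 33.5% (32.3 to 34.7) of the 6245 ectopic ones, a ratio of 1.25 (1.18 to 1.32). Neutrophils, the most numerous phagocytes of marrow, took 44.1% (43.1 to 45.1) in the femur and 36.6% (35.4 to 37.8) in the ectopic library, a ratio of 0.831 (0.790 to 0.875). Dendritic cells, which present antigen, took 1.103% in the femur and 2.74% in the ectopic library (ratio 2.48, 1.94 to 3.20). T and NK cells took 4.59% and 7.01% (ratio 1.53, 1.34 to 1.75).

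Myeloid progenitors, a class of 1 cluster led by Elane and Mpo and a larger one led by Fcnb and rich in Camp but poor in Mpo (18.6 CPM), were 5.92% of femur and 4.28% of ectopic cells (ratio 0.722, 0.622 to 0.836). Plasmacytoid dendritic cells, the main producers of type I interferon, were 3.01% and 1.31% (ratio 0.436, 0.337 to 0.559). Monocytes held 10.1% and 9.93% (ratio 0.987, 0.890 to 1.09), erythroid cells 0.861% and 0.849%, and basophils with mast cells 0.662% and 0.753%. The macrophage-like cluster had 16 femur and 3 ectopic cells. Clusters with no name under the marker rule held 2.70% of femur and 2.93% of ectopic cells. At a Leiden resolution of 0.5 the log2 share ratio of dendritic cells was 0.23 in place of 1.31, and at a resolution of 2 that of plasmacytoid cells was -0.52 in place of -1.20, since a cluster of B-like cells took that name through Ly6d. CAR-like cells were 2.41% of femur and 2.80% of ectopic cells, a share set by the mixing of the separately isolated fractions.

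**Figure D1:**
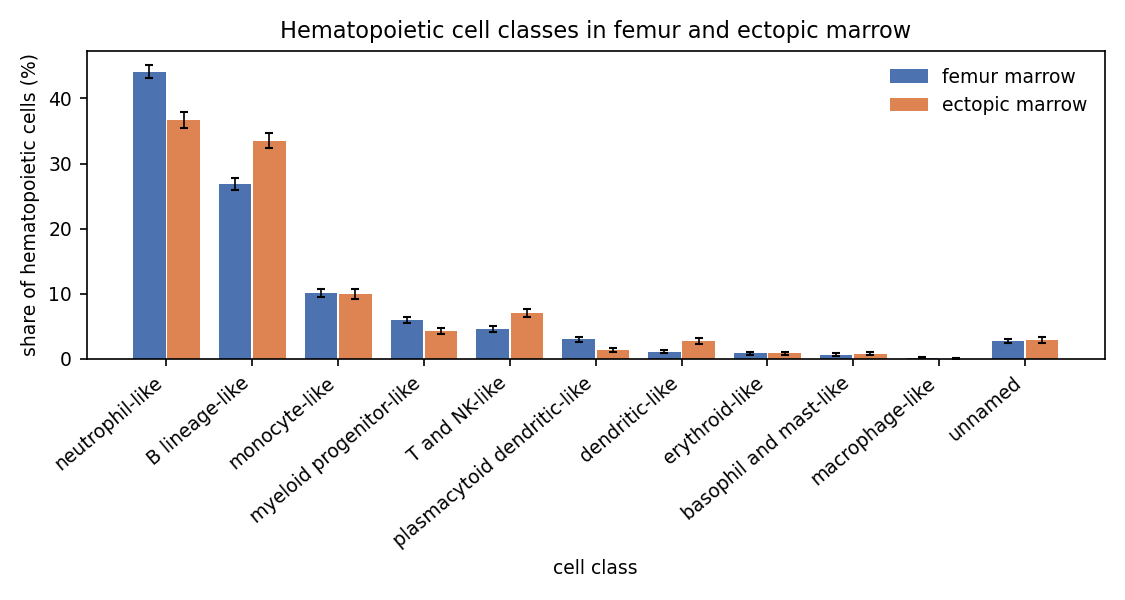
Share of cells outside stromal classes (percent, vertical axis) in each hematopoietic class (horizontal axis) of the femur library (blue) and the ectopic library (orange), with 1 library per group and black bars for the exact binomial 95% intervals of counting error. Neutrophils stood at 44.1% in the femur against 36.6% in the ectopic library, B lineage cells at 26.8% against 33.5%, and dendritic cells at 1.103% against 2.74%.

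Within the B lineage, ectopic marrow held more mature and fewer precursor cells. The cluster led by Ighd, Fcer2a and Cr2, which encode the IgD heavy chain and receptors of mature B cells, took 31.0% (29.2 to 32.8) of 2556 femur and 51.2% of 2093 ectopic B lineage cells, a ratio of 1.65 (1.51 to 1.81). The Ms4a1-led cluster, named for the gene of CD20, held 15.5% in the femur and 19.4% in the ectopic library. The Rag1-led cluster, whose gene encodes a recombinase of antigen receptor genes, held 28.8% and 18.0% (ratio 0.624, 0.550 to 0.707). The cluster led by Vpreb1 and Dntt, genes of the surrogate light chain and of terminal transferase in early precursors, held 9.59% and 4.49% (ratio 0.469, 0.365 to 0.597), and the cycling cluster 15.1% and 7.02% (ratio 0.464, 0.381 to 0.562). Of the 10 leading genes of each cluster, none was past 1.5-fold between libraries inside the Ighd-led, Rag1-led and cycling clusters. Inside the Vpreb1-led cluster 1 was, and inside the Ms4a1-led cluster 2 were. Cells of both libraries were clustered together and these genes picked from the clusters, so their likeness was in part set by that choice.

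**Figure D2:**
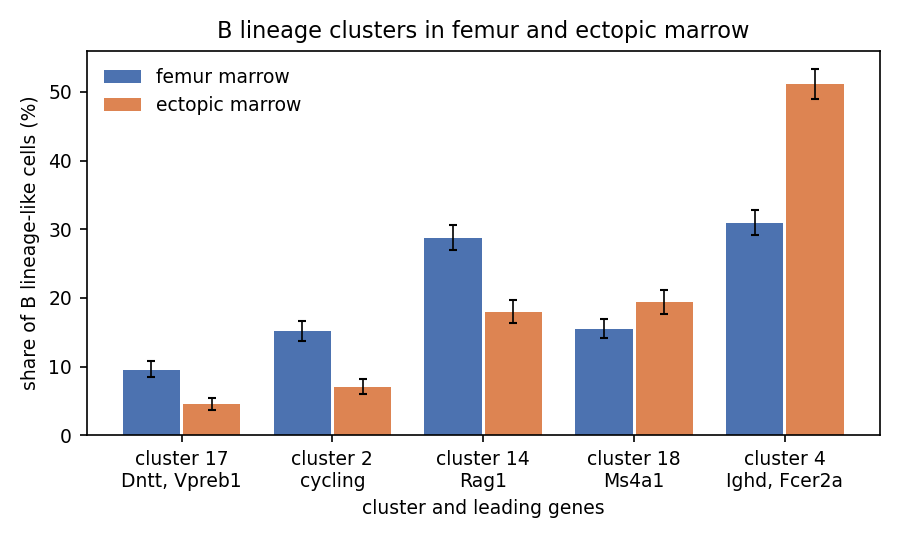
Share of B lineage cells (percent, vertical axis) in each B lineage cluster (horizontal axis, with leading genes) of the femur library (blue) and the ectopic library (orange), with 1 library per group and black bars for exact binomial 95% intervals of counting error. The Ighd-led cluster stood at 31.0% in the femur against 51.2% in the ectopic library, and the Vpreb1-led cluster at 9.59% against 4.49%.

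The main comparison asked how far CAR-like cells of ectopic marrow resemble those of the femur, gene by gene. Cxcl12 (ENSMUSG00000061353), the chemokine that retains stem cells and B precursors in marrow, stood at 8857 CPM in the femur and 9606 CPM in the ectopic library, a ratio of 1.08 (1.06 to 1.11). Kitl (ENSMUSG00000019966), which encodes stem cell factor, stood at 4229 and 3586 CPM (ratio 0.848, 0.821 to 0.875). Lepr (ENSMUSG00000057722), the leptin receptor gene that marks marrow CAR cells, was lower in the ectopic library, at 3153 against 1406 CPM (ratio 0.446, 0.426 to 0.466). Foxc1 (ENSMUSG00000050295) and Ebf3 (ENSMUSG00000010476), transcription factors that maintain CAR cells, were also lower there, with ratios of 0.506 (0.453 to 0.564) and 0.607 (0.584 to 0.631). The values came from 235 femur and 180 ectopic cells with medians of 9104 and 10435.5 UMIs. A minor cluster among them, led by the chemokine gene Cxcl9 and poor in the nuclear RNA Malat1, held 45 femur and 55 ectopic cells with medians of 1038 and 1450 UMIs and gave 2.69% and 6.35% of the summed UMIs. EGFP, the reporter transcript of the sorted mice, was at 634 and 931 CPM in these cells and at 0.3796 and 0.177 CPM in B lineage cells.

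Among the 15 niche factors, all measured, 5 were at least 1.5-fold higher and 1 at least 1.5-fold lower in the ectopic library, with a median log2 ratio of 0.30 (0.19 to 0.40) at percentile 97.3 of 10000 random lists of like expression. The highest ratios were those of Hgf, a hepatocyte growth factor gene, at 1.92 (1.26 to 2.95), of the lymphocyte cytokine gene Il15 at 1.90 (1.64 to 2.21) and of the Notch ligand gene Jag1 at 1.66 (1.30 to 2.13). Igf1 and the adhesion molecule gene Vcam1 each had a ratio of 1.59, Angpt1 one of 1.48, Gas6 one of 1.32, Csf1, the macrophage growth factor gene, one of 1.23 and Il34 one of 1.103. Ptn, which encodes the heparin-binding factor pleiotrophin, had 522 UMIs in the femur and 3 in the ectopic library (ratio 0.00627, 0.00129 to 0.0184). Il7, the cytokine gene of early B cell growth, had a ratio of 0.711 (0.594 to 0.849) and Fgf7 one of 0.759. Tnfsf11, the gene of the osteoclast factor RANKL, had one of 0.818, with 27.3% of its ectopic UMIs in 1 cell and 57.6% in 5 cells.

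The CAR identity list, also 15 of 15 measured, had a median log2 ratio of -0.02 (-0.16 to 0.10; percentile 33.4), with 3 members higher and 6 lower. Higher were the haptoglobin gene Hp, at 1453 against 5203 CPM (ratio 3.58, 3.44 to 3.73), the lipoprotein lipase gene Lpl (ratio 2.29, 2.20 to 2.39) and the angiotensinogen gene Agt (ratio 2.10, 1.89 to 2.35). Lower, beside Lepr, Foxc1 and Ebf3, were the growth factor receptor gene Pdgfrb (ratio 0.488, 0.448 to 0.531), Gdpd2 (0.547) and Esm1 (0.645). Adipoq, the adiponectin gene, had a ratio of 1.37 (1.30 to 1.44), Chrdl1, a BMP antagonist gene, one of 1.23, Ebf1 one of 1.09 and Cxcl14 one of 0.987. Across genes of at least 100 CPM in class sums thinned to the same number of UMIs, with cells and genes not matched, the median absolute log2 ratio was 0.286 in CAR-like cells, against 0.130 in neutrophils and 0.190 in B lineage cells, and 11.3% of these genes were at least 2-fold apart against 0.290% and 1.01%.

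**Figure D3:**
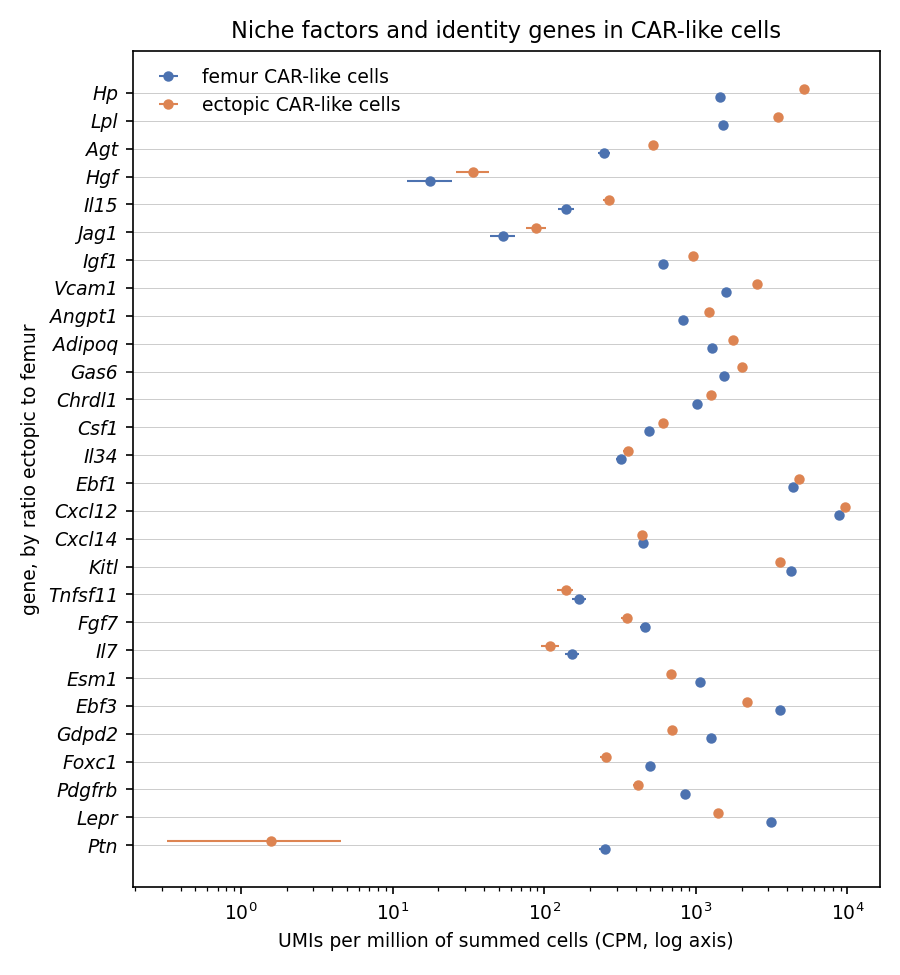
Level of each niche factor and CAR identity gene (CPM, log axis) in the summed femur (blue) and ectopic (orange) CAR-like cells, with genes ordered by their ratio, horizontal bars for exact Poisson 95% intervals of counting error and 1 library per group. Hp lay at 1453 CPM in the femur against 5203 in the ectopic library, Cxcl12 at 8857 against 9606, Lepr at 3153 against 1406 and Ptn at 250 against 1.57.

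Genes of the bone and fat lineages differed in CAR-like cells. Adipocyte genes were higher, with 6 of 10 measured members at least 1.5-fold higher, none lower and a median log2 ratio of 0.71 (0.58 to 0.84; percentile 99.97). The fatty acid carrier gene Fabp4 stood at 25.9 against 286.1 CPM (ratio 11.0, 8.34 to 14.9), with 62.96% of its femur and 52.1% of its ectopic UMIs in 5 cells, and Cebpa, a factor of fat cell differentiation, had a ratio of 2.55 (2.11 to 3.08). The lowest were Zfp423 at 0.952 and Pparg, the master factor of fat cells, at 1.16. Osteoblast genes split, with 6 of 11 higher, 3 lower and a median of 0.76 (0.30 to 0.93; percentile 99.99), which was -0.22 with every cell thinned to 3000 UMIs and -0.08 without doublet removal. Ibsp (ENSMUSG00000029306), the bone sialoprotein gene, was at 5341 CPM in femur and 954 CPM in ectopic CAR-like cells (ratio 0.179, 0.170 to 0.188). Phex, an endopeptidase gene of mineral regulation, and Runx2, the master factor of osteoblasts, had ratios of 0.165 (0.121 to 0.222) and 0.338 (0.319 to 0.357). Col1a1, the main collagen of bone, stood at 122 against 595 CPM (ratio 4.86, 4.24 to 5.59), but 5 cells held 56.6% of its ectopic UMIs. Spp1, the osteopontin gene, had a ratio of 2.52 (2.15 to 2.97) with 39.0% of its ectopic UMIs in 1 cell, and its log2 ratio turned from 1.34 to -1.85 without doublet removal.

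Among the lists in CAR-like cells, Hox groups 9 to 13 had the median farthest from 0. Hox genes of paralogue groups 9 to 13, which are used in the posterior trunk and the limb, had a median log2 ratio of -1.96 (-2.41 to -1.52), below all 10000 random lists, with 3 of 4 measured members lower. Hoxa10 stood at 96.9 against 15.2 CPM (ratio 0.157, 0.102 to 0.232), Hoxc10 and Hoxa9 had ratios of 0.256 (0.135 to 0.454) and 0.260 (0.179 to 0.368), and Hoxc9 one of 1.34 (0.900 to 1.99). Hox genes of groups 1 to 8 had a median of 0.76 (0.37 to 1.25; percentile 100), with 6 of 12 higher and 3 lower, and a median of 1.52 with members counted from 20 UMIs. Hoxb6 had 4 femur and 48 ectopic UMIs (ratio 13.1, 4.79 to 49.97) and Hoxc8 stood at 16.8 against 78.96 CPM (ratio 4.70, 3.24 to 7.004), while Hoxa5 and Hoxa3 had ratios of 0.304 and 0.378. All measured Hoxa genes were lower, whichever their group, and all measured Hoxb genes were higher. The limb and trunk patterning factors had a median of -0.16 (-0.26 to -0.06), with 3 of 11 higher and 4 lower. En1, a dorsoventral patterning factor, had 2 femur and 51 ectopic UMIs (ratio 27.8, 7.31 to 236), Twist1 a ratio of 1.75 that reversed to a log2 ratio of -0.26 in thinned cells, and Twist2 and the limb factor Shox2 ratios of 0.308 and 0.349.

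Of the fibroblast and extracellular matrix list, 8 of 15 measured members were higher and 1 lower, with a median of 0.60 (0.42 to 0.90; percentile 99.98), 0.13 in thinned cells and 0.24 as a mean of per-cell CPM. The microfibril gene Mfap5 had 0 femur and 64 ectopic UMIs, at least 23.3-fold higher against a floor of 3 UMIs, and the fibronectin gene Fn1 a ratio of 8.69 (5.97 to 13.1) at levels below those of other cells (189 and 229 CPM). Fbn1, the fibrillin gene, was lower at 0.384 (0.357 to 0.413) and Tnc stood at 0.878. The inflammatory list had 7 of 13 higher, 2 lower and a median of 0.87 (0.37 to 1.17; percentile 100). The neutrophil gene Camp stood at 271 against 801 CPM in the same cells and S100a8 at 2693 against 25097 CPM in their low-UMI cluster, and without that cluster the inflammatory median was 0.26, with 6 members higher and 4 lower. The top inflammatory genes were Saa3, an acute phase gene, with 1 femur and 96 ectopic UMIs (ratio 104.7, 18.3 to 4177) and 86.5% of the ectopic ones in 5 cells, and the neutrophil chemokine gene Cxcl5 with 3 and 77 (ratio 28.0, 9.23 to 139). Of other higher members, Lcn2 had 74.96% of its ectopic UMIs in 1 cell and Ccl2 64.2% in 5 cells. Ccl19 was at 0.526, and Cxcl10 at 0.625 with most of its UMIs in 1 cell of each library and a reversed log2 ratio of 1.37 as a mean of per-cell CPM.

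The dissociation and immediate early list, which rises with enzymatic digestion, had 11 of 18 higher, none lower and a median of 0.71 (0.63 to 0.79; percentile 100). The heat shock genes Hspa1a and Hspa1b had ratios of 5.65 (3.99 to 8.18) and 4.50 (3.34 to 6.16), with 58.9% and 61.2% of their ectopic UMIs in 5 cells, and Ier3 and Dusp1 ratios of 0.740 and 0.907. Interferon-stimulated genes had a median of -0.38 (-0.51 to -0.06; percentile 0.195), with 1 of 15 higher and 3 lower. Bst2 and Isg15 had ratios of 1.55 and 1.36, Ifi44 one of 0.230 (0.125 to 0.397) and Gbp2 one of 0.473, with a log2 ratio of 0.20 for Gbp2 as a mean of per-cell CPM.

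BMP signalling targets and antagonists went both ways, with 3 of 11 higher, 3 lower and a median of 0.20 (-0.03 to 0.40; percentile 85.8). Bmp6, a BMP ligand gene, was at 1999 CPM in the femur and 333 CPM in the ectopic library (ratio 0.166, 0.153 to 0.181), and Id4 had a ratio of 0.417. Id3, a BMP target, had a ratio of 2.25 (2.04 to 2.49), and Id1 one of 5.65 (2.93 to 12.0) at levels near or below those of other cells (29.4 and 25.8 CPM). Cartilage genes had a median of 1.17 (0.62 to 1.65) over 3 measured members, with Sox5 at 3.09 (2.57 to 3.73), Comp at 2.25 and Sox9, the master factor of cartilage, at 1.21 (0.827 to 1.76). The median is the value of Comp, which had 64 ectopic UMIs in 13 cells and 31 femur UMIs in 11, with 79.7% and 80.7% of them in 5 cells. Hypoxia and glycolysis genes had a median of 0.49 (0.09 to 0.64), with 4 of 10 higher and 2 lower. They ranged from Hk2 at 2.31 (a log2 ratio of -0.10 in thinned cells) and Ldha at 1.60 to Ndrg1 at 0.621 and Vegfa at 0.597. Ndrg1 had 51.3% of its ectopic UMIs in 1 cell. The 3 measured proliferation genes Stmn1, Mcm6 and Hmgb2 had ratios of 1.25, 1.12 and 1.04. The 3 measured MHC class II genes Cd74, H2-Aa and H2-Eb1 had ratios of 1.89, 1.82 and 1.75 at levels far below other cells, and without doublet removal the median of 0.86 turned to -0.06.

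**Figure D4:**
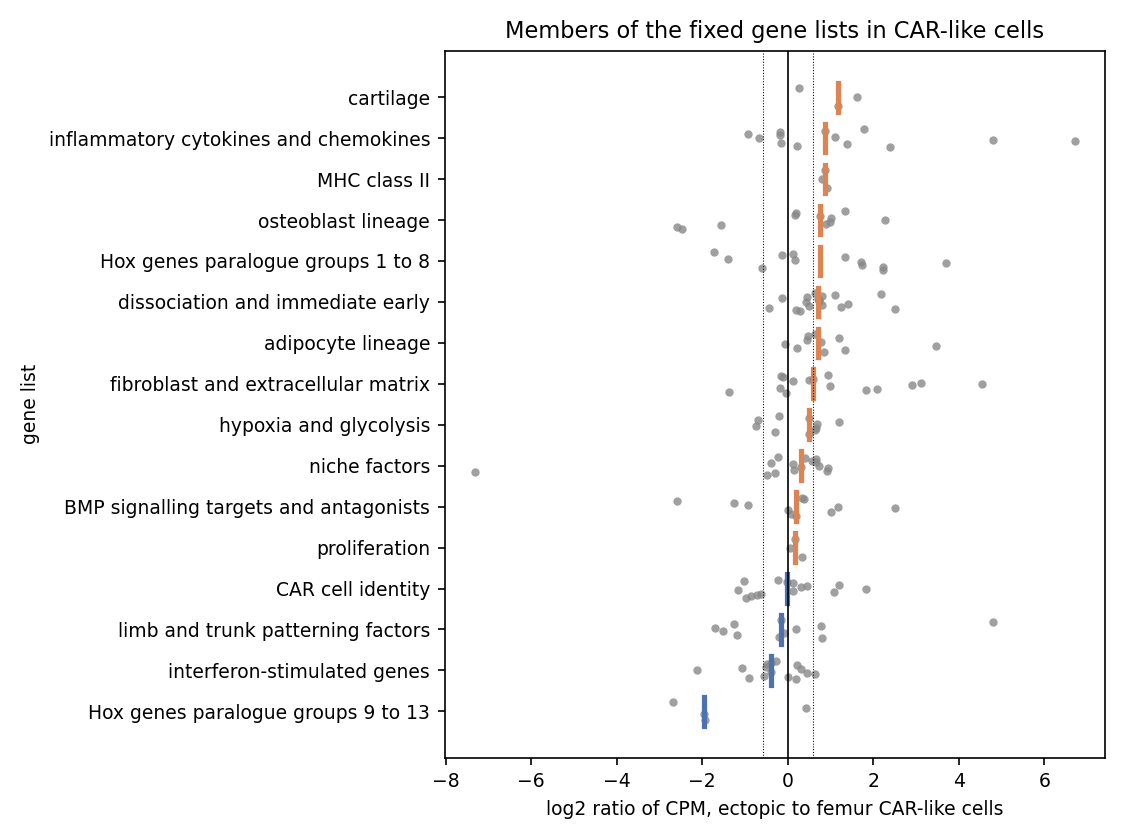
Log2 ratio of CPM, ectopic to femur CAR-like cells (horizontal axis), of each measured member (grey points) of the fixed gene lists (vertical axis), with thick marks for list medians (orange above 0, blue below), dotted lines at a 1.5-fold difference, no error bars and 1 library per group. The Hox genes of groups 9 to 13 had the lowest median at -1.96, and the cartilage list of 3 genes the highest at 1.17, the value of Comp, which rests on a few cells.

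The rule for single genes took the 10 highest and 10 lowest ratios among 2064 eligible genes of CAR-like cells. Highest were the ephrin receptor gene Epha3, at 8.15 against 217 CPM (ratio 26.6, 16.4 to 46.1), the carbonic anhydrase gene Car3 (22.7, with 70.3% of its ectopic UMIs in 5 cells), the amino acid transporter gene Slc36a2 (11.3), Fabp4, the metallothionein gene Mt2 (9.03), Fn1, Itih5 (6.13), Pdzd2 (5.997), the nuclear receptor gene Nr2f2 (5.88) and Angptl4, an inhibitor of lipoprotein lipase (5.69). Lowest was Aldh1a2, which encodes an enzyme of retinoic acid synthesis, with 1198 femur and 3 ectopic UMIs (ratio 0.00273, 0.000562 to 0.00800). Tenm2, a teneurin gene, had 636 femur and 0 ectopic UMIs, and Adarb2 257 and 0. Femur CAR-like cells held 264 UMIs of Cobl, 524 of Rtl4 and 412 of Eya1, a transcriptional coactivator gene, against 1, 2 and 3 in the ectopic ones. Pdzrn4 stood at 2116 against 40.3 CPM (ratio 0.0190, 0.0150 to 0.0238), with ratios of 0.0229 for Mpped2 and 0.0255 for the neuregulin gene Nrg3, and Ptn completed this group.

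Detection per cell was compared after each cell was thinned to 3000 UMIs, which left 177 of 235 femur and 131 of 180 ectopic CAR-like cells. Cxcl12 was seen in 100% of femur and 98.5% of ectopic cells, Kitl in 100% and 96.2%, and Lepr in 98.9% (95.98 to 99.9) and 92.4% (86.4 to 96.3). Foxc1 was seen in 71.2% (63.9 to 77.7) and 46.6% (37.8 to 55.5), and Ebf3 in 99.4% and 92.4%. Ibsp was seen in 93.2% (88.5 to 96.4) of femur and 29.0% (21.4 to 37.6) of ectopic cells, and Col1a1 in 20.3% (14.7 to 27.0) and 47.3% (38.5 to 56.2). Il7 was seen in 32.2% and 20.6%, Csf1 in 68.4% and 71.0%, Vcam1 in 94.9% and 95.4%, Adipoq in 78.0% and 77.9% and EGFP in 67.2% and 66.4%. Without thinning the shares were 98.7% and 99.4% for Cxcl12, 96.2% and 92.2% for Lepr, 77.9% and 63.3% for Foxc1, 87.2% and 77.8% for Ebf3, 91.5% and 33.3% for Ibsp, 52.8% and 45.6% for Il7 and 35.3% and 60.0% for Col1a1. In B lineage cells, which should lack these transcripts, 2462 of 2556 femur and 2069 of 2093 ectopic cells passed the same thinning from medians of 5985.5 and 6480 UMIs. There Cxcl12 was seen in 2.84% and 1.98%, Csf1 in 2.36% and 1.498%, Ibsp in 1.22% and 0.290%, Col1a1 in 0.731% and 1.30%, Il7 in 0.0812% and 0.145%, Lepr in 0.690% and 0.628%, Ebf3 in 0.528% and 0.338%, and Foxc1 in 0.162% and 0.145%.

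The remaining comparison took each hematopoietic class with at least 100 cells in both libraries. In neutrophils, 3 of 10 measured inflammatory genes were lower in the ectopic library, none was higher and 7 stayed within 1.5-fold, with a median log2 ratio of -0.31 (-0.45 to -0.18; percentile 0.02). The lowest were Icam1, an adhesion molecule gene, at -1.82 and Nfkbia, an NF-κB inhibitor gene, at 1689 against 842 CPM (ratio 0.499). Mature neutrophil genes had a median of -0.21 (-0.24 to -0.17), with Wfdc17 (ratio 0.315) and the chemokine gene Cxcl2 (1437 against 773 CPM, ratio 0.538) lower and S100a9 and S100a8 at 0.07 and 0.03. The dissociation list, with 2 higher and 2 lower of 16, had a median of -0.30, from Fosb at 0.91 to Dusp1 at -1.10. Primary granule genes had a median of 0.14, with the azurophil protease and peroxidase genes Ctsg and Mpo at -1.01 and -1.15, and secondary granule genes one of 0.07 with none of 10 past 1.5-fold. Mpo stood at 11.2 to 22.4 CPM in the neutrophil clusters, near the 13.3 CPM of the T cell cluster. In the Elane-led progenitor cluster it stood at 4067 CPM, so free RNA was not excluded as its source in neutrophils. Proliferation genes (3 of 16 higher, Cenpf at 0.67 and Tpx2 at 0.60), emergency myelopoiesis genes, interferon-stimulated genes and hypoxia genes had medians of 0.12, -0.10, -0.06 and 0.00. The highest single genes, Hmgn2, Scp2, Slc31a2, Eno1, Gpx4, Cyba, Aprt, Capg and Camp, had ratios of 1.39 to 1.26. The 10 lowest, which beside Wfdc17, Nfkbia and Cxcl2 were Ifitm1, Dusp1, Tnfaip3, Nlrp3, Tsc22d3, Acod1 and Pde4b, had ratios of 0.315 to 0.609. The neutrophil cluster led by Il1b and Ptgs2 held 26.2% of femur and 19.0% of ectopic neutrophils.

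Monocytes of ectopic marrow had higher interferon-stimulated genes. Of 18 interferon-stimulated genes, 10 were higher and none lower, with a median of 0.59 (0.46 to 0.64; percentile 100) and the antiviral genes Ifit2 and Ifi44 at 1.15 and 1.13. Of 7 MHC class II genes, which serve antigen presentation, 3 were higher, with a median of 0.53 (0.44 to 0.62) and their transactivator gene Ciita at 1.58. The higher genes Ciita (2.87 against 8.57 CPM), H2-Aa (18.2 against 34.5) and H2-Ab1 (15.1 against 28.7) and the median gene Cd74 (124 against 179) lay below the levels of other cells, which were 25.96 against 52.0, 345 against 767, 245 against 572 and 712 against 1661. Free RNA was therefore not excluded as their source. The dissociation list had a median of -0.29 (-0.32 to -0.25) with 1 of 18 higher, Ier3 at 0.65, and 4 lower, among them Hspa1b at -2.71 and Hspa1a at -1.44. Inflammatory genes had a median of 0.12, with the chemokine gene Ccl2 at 0.88 and Nfkbia at -0.62, and emergency myelopoiesis, proliferation and hypoxia genes had medians of 0.04, -0.06 and 0.00 with none past 1.5-fold. Single genes with the highest ratios were the histone gene H2ac24 (3.31), Lpl (2.55), H2-T23, the calcium-binding protein gene S100a4 (1.499), Esd, Ifi211, Capg, Arhgef37 and Aprt (1.40). Those with the lowest were the granule protease gene Elane, at 706 against 235 CPM (ratio 0.334), Mpo (0.339), Fkbp5, Klf9, Prtn3, Tsc22d3, Ctsg, Dusp1, H1f2 and Apoe (0.602). Of monocytes, the Ccr2-led cluster held 51.0% in the femur and 61.5% in the ectopic library, the Ace-led cluster, in which Apoe was a leading gene, 18.9% and 11.9%, and the F13a1-led cluster, rich in Elane and Mpo, 30.1% and 26.6%.

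B lineage cells of ectopic marrow had higher late and lower early genes as a class. Of 12 late B cell genes 10 were higher, with a median of 0.76 (0.74 to 0.81), and of 13 early genes 7 were lower, with a median of -0.61 (-0.65 to -0.56) and Dntt and Erg at -1.22 and -0.97. All 7 MHC class II genes were higher (median 0.94, 0.92 to 0.98), with the invariant chain gene Cd74 at 1971 against 4197 CPM (ratio 2.13), and all 16 proliferation genes lower (median -0.87, -0.90 to -0.83), with the topoisomerase gene Top2a at -1.07. The Ighd-led cluster held 31.0% of femur and 51.2% of ectopic B lineage cells. Inside it none of 7 MHC class II and none of 12 late genes passed 1.5-fold, with medians of 0.10 and 0.05. The late genes Ighd, Fcer2a, Fcmr and Cr2 and the MHC class II gene H2-Eb1 lead that cluster. Likeness inside it was therefore in part set by the clustering. Interferon-stimulated and dissociation genes had medians of 0.10 and 0.00 and no more than 2 members past 1.5-fold in either direction. The highest single genes were Setbp1 (2.20), Ctsh, the lymphotoxin gene Ltb (2.14), Cd74, H2-Aa, H2-Eb1, Grap2, H2-Ab1 and H2-DMa (1.91). The lowest were Dntt (0.428), Nusap1, Arpp21, Kif11, Top2a, Lockd, Neil3, Kif23, Cenpe and Fbxo5 (0.492).

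Myeloid progenitors of ectopic marrow had lower stem cell genes. Of 12 measured stem cell and self-renewal genes, 11 were lower, with a median of -1.22 (-1.42 to -1.08), below all random lists. The surface antigen gene Ly6a and Ifitm1 lay at -3.32 and -1.98, and the highest were Cd34 at 0.07 and Kit, the receptor gene of stem cell factor, at -0.59. At a Leiden resolution of 2, stem and progenitor cells formed a cluster of their own with 104 femur and 23 ectopic cells (1.09% and 0.368% of cells outside stromal classes). The stem cell median of the progenitor class was then -0.61. Primary and secondary granule genes had medians of -0.01 and 0.07 with none past 1.5-fold, and emergency myelopoiesis, interferon-stimulated, dissociation and proliferation genes medians of -0.02, -0.30, -0.12 and 0.09. Highest were the histone gene H2ac24, at 519.9 against 2213 CPM (ratio 4.26), H2ac8, H2ac4, Zmpste24, Rbm3, Pgp, Alyref, Larp1b and H2ac10 (1.37). Lowest were Angpt1 (0.399), Gcnt2, the homeobox gene Meis1 (0.503), Adgrl4, Msi2, Maml3, Fut8, Gas5 and Myb (0.674). The cluster led by Fcnb and Cebpe held 67.4% of femur and 73.0% of ectopic progenitors.

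T and NK cells had few genes at least 2-fold apart, 0.166% of 1803 in class sums thinned to the same number of UMIs. Their median absolute log2 ratio was 0.149, against 0.130 in neutrophils. Interferon-stimulated genes had a median of 0.27 (0.08 to 0.41; percentile 99.96) with 3 of 16 higher, led by Ifit1 at 1.02 and Isg15 at 0.95. Proliferation genes had a median of -0.34 with 4 of 15 lower, and dissociation genes one of -0.02. Inflammatory genes had a median of 0.09 with 3 of 7 higher and 1 lower. Highest were the chemokine gene Cxcl10 at 2.72 (13 against 111 UMIs, ratio 6.58, 3.69 to 12.7) and Tnf at 1.05. The lower gene was Cxcl2, at 11.8 against 5.81 CPM, far below its 571 and 297 CPM in other cells. Free RNA was therefore not excluded as the source of Cxcl2. Zbtb16, which encodes the PLZF factor of innate-like T cells, was lowest at 108 against 22.2 CPM (ratio 0.206, 0.165 to 0.255), followed by Tsc22d3 (0.579), Dhx40, Chn2, Zfp36l2, Rora, Ccr2, Btbd11, Icos and Lyst (0.636). The chemokine gene Ccl4 (92.1 against 199 CPM, ratio 2.16), Rbm3, Ms4a4c, Slc25a4, Tmem163, Pam, Tnfsf8, Traf1 and Ppp1r14b (1.39) were highest. The T cell cluster held 83.5% of femur and 86.1% of ectopic cells of this class.

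Dendritic cells, with 105 femur and 171 ectopic cells, had lower proliferation genes, 10 of 16 lower and none higher, with a median of -0.63 (-0.81 to -0.54). That median was 0.00 when only cells of at least 1500 UMIs were taken, and the kinetochore gene Cenpf turned from -1.22 to 0.03. Cells were clustered anew there and the class held 91 femur and 149 ectopic cells, so a change of members cannot be told apart from UMI number. Their 7 MHC class II genes lay between 0.27 and 0.43 with a median of 0.29 (0.28 to 0.37). Inflammatory, interferon-stimulated and dissociation genes had medians of 0.20, -0.04 and -0.03, with the chemokine gene Cxcl9 at 2.28 and Ccl2 at -1.25. The inflammatory median is the value of Lcn2, at 44.0 against 50.7 CPM, far below its 4961 and 4202 CPM in other cells. Free RNA was therefore not excluded as the source of Lcn2. Ccl5, a T cell chemokine gene, stood at 19.96 against 153 CPM (ratio 7.65, 5.26 to 11.6), followed by Ly6c2 (2.19), Tmem123, Pltp, H2ac24, Naaa, Clec10a, Aif1 and the complement gene C1qb (1.77). The lowest were Auts2 (0.242), Lockd, Adgrl3, Kif11, Prc1, Cenpf, Nusap1, Kif15, Top2a and Rad51b (0.460).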

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

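The tests of damaged cells and of free RNA for the Hox genes, of a few cells and of osteoblast-like cells for Ibsp, and of blood and of UMI number for the B lineage were chosen after the results were seen, and those of free RNA for Ibsp and of low depth for the B lineage before.

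Cells set aside by the doublet score held a signal in data outside the comparisons. Among 1279 such cells, 6 had at least 1 percent of their UMIs in Col1a1 (2 femur, 4 ectopic), against 0 of the cells kept. Summed, they had 122572 CPM of Col1a1, 6478 of the osteocalcin gene Bglap, 4428 of Ibsp and 53.95 of the pan-hematopoietic gene Ptprc, with a median of 36475.5 UMIs. They are values of osteoblast-like cells that the comparisons do not hold, and no explanation for their score was tested.

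Hox genes set the libraries apart in CAR-like cells: the median log2 ratio of groups 1 to 8 less that of groups 9 to 13 was 2.71. The measured genes also divide by the letter of their name. Hoxa genes of both ranges were all lower, from -0.60 for Hoxa7 to -2.68 for Hoxa10. Hoxb genes were all higher, from 1.71 for Hoxb2 to 3.71 for Hoxb6. The contrast of paralogue groups can therefore not be told apart from one of Hoxa against Hoxb genes. The low-UMI cluster, which was poor in the nuclear RNA Malat1 and may hold damaged cells, gave 2.69% of femur and 6.35% of ectopic summed UMIs. Leaving it out could therefore hardly move the difference, which was then 2.66 and so lay in the other CAR-like cells. The difference was between 2.51 and 3.09 under the other settings for which it was computed. The tables argue against free RNA of hematopoietic cells, since in the library where each gene was higher its CPM in other cells was 0.00380 of that in CAR-like cells at the median. The site of the tissue, femur against an implant under the skin at a place the labels do not state, stays open as untested, and so does a difference between animals.

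Ibsp was lower in ectopic CAR-like cells, at 954 against 5341 CPM. Against free RNA in the femur library stands its level in femur B lineage cells, 0.0648 percent of that in CAR-like cells, and against a few cells of very high level the median thinned femur cell, which held 13 Ibsp UMIs. Col1a1 stood at 0.0229 of Ibsp in femur CAR-like cells, which argues against osteoblast-like cells rich in Col1a1 as the source. In the cells left out by the doublet score it stood at 27.7 of Ibsp over both libraries. That value was in part set by their choice for high Col1a1. Osteoblast-like cells with high Ibsp and little Col1a1 were therefore not excluded. In the ectopic library 66.0% of Ibsp UMIs lay in 5 cells, so the remaining cells held less than the sum shows. The tissue of origin and the age of the bone stay open as untested, and lower Ibsp in CAR-like cells of the implant is a hypothesis only.

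Mature B cells took more and B precursors less of the B lineage in ectopic marrow. A minimum of 1500 UMIs gave a ratio of the Ighd-led share of 1.65 but left out only 0.409% of B lineage cells, so it decides nothing. The ratio was 2.31 (1.97 to 2.71) among B lineage cells at or above their median of 6235 UMIs and 1.44 (1.28 to 1.62) below it. The ectopic share was higher on both sides, which argues against UMI number as the whole cause. The size of the ratio did vary with UMI number. Ectopic cells of the Ighd-led cluster also had more UMIs (median 6141 against 5330), so the cut did not match depth between libraries. Blood in the ectopic harvest is argued against as the whole cause by the Ace-led monocyte cluster, whose marker is typical of circulating monocytes and whose share of hematopoietic cells had a ratio of 0.623 (0.469 to 0.821), and by the Il1b-led neutrophil cluster at 0.603 (0.538 to 0.675), while T and NK cells at 1.53 go with blood. Immature neutrophils of the Ltf-led cluster, which blood would dilute, had a ratio of 1.02 (0.903 to 1.16), and erythroid cells one of 0.985 (0.684 to 1.41). Myeloid progenitors, which blood would also dilute, had a ratio of 0.722 (0.622 to 0.836) and go with blood. So does the stem and progenitor cluster at a Leiden resolution of 2, with a ratio of 0.337 (0.205 to 0.534). The tissue itself stays open as untested, and so do the isolation of hematopoietic cells and a part played by blood.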

How the results depend on the processing

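No paired analysis was possible because each group had 1 library and nothing in the labels pairs them. The settings without the low-UMI cluster and with only EGFP cells were chosen after seeing the data. Of the main values, 42 of 48 for class shares kept their value within counting error, 42 of 55 for CAR-like genes, 77 of 84 for CAR-like lists, 31 of 44 for hematopoietic lists and 16 of 20 for detection; of the others, 915 of 1034 CAR-like gene, 467 of 524 CAR-like list, 458 of 588 hematopoietic, 18 of 20 share and 16 of 24 detection values did. The macrophage share had no value at a resolution of 0.5, at 1500 UMIs, at 5% mitochondrial UMIs or with each library alone, as no cluster took that name. The CAR-like comparison rests on 235 and 180 cells. Values are log2 ratios with the main value in brackets, and the cause was not tested unless given.

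Counting members from 20 UMIs, which adds genes of low count, gave 1.52 (0.76) for Hox groups 1 to 8. A Leiden resolution of 0.5, which merges clusters, gave shares of 0.23 (1.31) for dendritic cells and 0.28 (-0.02) for monocytes. A resolution of 2 gave -0.23 (-0.47) for the myeloid progenitor share, with 565 femur and 316 ectopic cells in the class (564 and 267), -0.52 (-1.20) for plasmacytoid dendritic cells, and in progenitors -0.14 (-0.01) for primary granule and -0.61 (-1.22) for stem cell genes. TMM gave 0.074 for primary granule genes. At 1500 UMIs or more, with cells clustered anew, the progenitor share was -0.23, primary granule genes -0.15, stem cell genes -0.63 and mature neutrophil genes -0.16 (-0.21). Dendritic cells then had MHC class II genes at 0.23 (0.29), proliferation genes at 0.00394 (-0.63, reversed) and Cenpf at 0.032 (-1.22, reversed). With each library clustered alone the progenitor share was -0.12.

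Means of per-cell CPM, which give small cells equal weight, gave 0.33 (0.12) for Cxcl12, -0.84 (-0.72) for Ebf3, -1.06 (-1.17) for Lepr, -2.60 (-2.48) for Ibsp, and reversed Cxcl10 to 1.37 (-0.68), Gbp2 to 0.20 (-1.08) and H2-Eb1 to -0.44 (0.81). Lists became 0.18 (0.76) for osteoblast, 0.24 (0.60) for matrix, -0.010 (-0.06) for neutrophil interferon, -0.77 (-0.61) for early and 0.58 (0.76) for late B cell, 0.074 for progenitor primary granule, -1.63 for stem cell and 0.27 for dendritic MHC class II genes. Median-of-ratios scaling gave 0.087 for Cxcl12. No doublet removal left 288 femur and 199 ectopic CAR-like cells, in place of 235 and 180. Which of the returned cells set the changed values was not tested. This setting gave 0.23 for Cxcl12, -0.60 for Ebf3, -0.78 (-0.98) for Foxc1, -1.003 for Lepr and -2.09 for Ibsp. It reversed Spp1 to -1.85 (1.34), Cxcl10 to 0.64, Cd74 to -0.057 (0.91) and H2-Eb1 to -0.090. The osteoblast list was reversed to -0.075 and the MHC class II list to -0.057 (0.86). Thinned cells reversed Twist1 to -0.26 (0.81), Cxcl10 to 1.67, Hk2 to -0.10 (1.21) and the osteoblast list to -0.22, with 0.13 for matrix genes.

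Only EGFP cells gave 0.070 for Cxcl12, -2.88 for Ibsp and 0.35 for matrix genes, and leaving out the low-UMI cluster gave 0.079 for Cxcl12. The CAR-like inflammatory list (0.87) gave 0.22 at 1500 UMIs or more, 0.33 without doublet removal, 0.21 with each library clustered alone, 0.30 in cells with no Ptprc UMI and 0.26 without the low-UMI cluster. Without thinning, Foxc1 was seen in 77.9% of femur (71.2) and 63.3% of ectopic cells (46.6), and Ebf3 in 87.2% (99.4) and 77.8% (92.4); cells then keep all their UMIs, and those under 3000 UMIs are counted.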

Other observations

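These values were chosen after they were seen, and the stem cell cluster and H2ac24 also appear above. At a Leiden resolution of 2, hematopoietic stem and progenitor cells formed a cluster of their own with 104 femur and 23 ectopic cells. These were 1.09% (0.893 to 1.32) and 0.368% (0.234 to 0.552) of cells outside stromal classes, a ratio of 0.337 (0.205 to 0.534). At a resolution of 0.5 the cluster of that name, whose leading genes included F13a1 and Gria3 of monocytes, had 422 and 218 cells (4.43% and 3.49%, ratio 0.787, 0.666 to 0.930). Inside single B lineage clusters, proliferation genes were lower in the ectopic library in the Ighd-led cluster (6 of 9 lower, median log2 ratio -0.88), the Ms4a1-led cluster (8 of 9, -1.24), the Rag1-led cluster (6 of 8, -0.71) and the Vpreb1-led cluster (7 of 16, -0.51). In the cycling cluster none of 16 passed 1.5-fold and the median was -0.09. The proliferation gene Mki67 stood at 8.4, 24.8 and 12.4 CPM in the Ighd-led, Ms4a1-led and Rag1-led clusters. It stood at 468 CPM in the Vpreb1-led and 1063 CPM in the cycling cluster. Free RNA was therefore not excluded as the source of proliferation genes in the Ighd-led, Ms4a1-led and Rag1-led clusters. MHC class II genes had medians of 1.26 in the Vpreb1-led cluster (2 of 4 higher, 1 lower), 0.43 in the Ms4a1-led, 0.10 in the Ighd-led, -0.11 in the Rag1-led and -0.14 in the cycling cluster.

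The histone gene H2ac24 was higher in the ectopic library in 9 classes outside the stroma, from a ratio of 1.63 in basophils and mast cells to 5.66 in plasmacytoid dendritic cells. No explanation for this was tested.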
